A study of Mus musculus with 12 samples.

How the data were processed

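RNA from the terminal ileum of 12 male mice was sequenced, 1 library per mouse, in 4 groups of 3 mice. The groups were wild type C57BL/6 mice, Rag1−/− mice, Tcra−/− mice kept in 1 cage with wild type mice for 4 to 8 weeks (co-housed), and Tcra−/− mice kept apart (separately housed). Per the labels' protocols, the mice came from Taconic and were kept in a specific pathogen free facility, RNA was taken up in Trizol and stranded mRNA libraries were made with an Illumina kit. The replicates were separate mice, and the labels give no pairing and no sequencing batch. The number of cages per group is not known here, and mice that share a cage are not independent replicates of housing. Tests of the housing comparison therefore measure spread among mice, not among cages. Single mice are named as on the labels, with WTB6x for wild type, RAG1x for Rag1−/−, TCRaCox for co-housed and TCRaSepx for separately housed Tcra−/− mice.

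Per the submitters' processing notes, reads were converted with bcl2fastq, aligned to mm9 with TopHat2 2.0.11 and Bowtie2 2.2.2.0, counted per gene with featureCounts of Subread 1.4.5-p1, and tested by the authors with DESeq2 1.12.3. The deposited values are raw counts of reads per gene with no normalization, per the file headers and the values, which are whole numbers. The same table gives a gene length in bases of merged exons, per the file headers, which was not used. The gene annotation, the strand setting and the treatment of multi-mapped reads are not given in the sources used here. Reads from overlapping genes, antisense partners and near-identical paralogs can therefore be assigned to either gene. Of the genes tested, 1980 share exonic bases with another gene on either strand, and 41 pairs on 1 strand have identical counts. Gene symbols and mm9 coordinates are those of the deposited table.

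The table holds 23284 genes, of which 3810 had no read in any library. The total per library ran from 37061276 to 50581616 counts. The filter filterByExpr of edgeR 4.0.16, applied to the 4 groups, kept 15866 genes. Factors from the trimmed mean of M-values (TMM) ran from 0.926 to 1.07. A quasi-likelihood model (robust, 1 term per group, 8 residual degrees of freedom) was fitted to all 12 libraries in R 4.3.3, and contrasts were tested two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.01, the false discovery rate of the design text, were called. An adjusted p of a gene in the text comes from this test. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Values in CPM are counts scaled to the TMM-normalized library size, given as mean ± SD of 3 mice. For a gene with no read in 1 group, the fold is a lower bound against a floor of 3 counts over that group. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. Intervals of odds ratios treat genes as independent units, which they are not.

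Two-sided tests were made for Rag1−/− against wild type and for co-housed against separately housed Tcra−/− mice, the comparisons of the design text. Each Tcra−/− group was also compared with wild type, for the closing section. The genes called in both stated comparisons were counted and tested with Fisher's exact test, two-sided, per direction.

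A total of 34 gene lists was fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. They cover the IL-22 and STAT3 epithelial response, Paneth cells, T cells, cytotoxic and intraepithelial lymphocytes, B cells, plasma cells, group 3 innate lymphoid cells with their cytokines, myeloid cells, MHC class II, the interferon gamma and type I interferon responses, lipid absorption, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, bile acid handling, xenobiotic and retinoid metabolism, brush border digestion, goblet, tuft and enteroendocrine cells, crypt proliferation, smooth muscle, fibroblasts, endothelium, enteric neurons and glia, adipocytes, pancreas acinar cells, red blood cells, proximal small intestine, colon, circadian clock, immediate early genes with heat shock, and sex-linked transcripts. Lists with at least 4 tested members, 32 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. The pancreas acinar and colon lists had 3 tested members each and were not tested. The red blood cell list was tested on 5 members, of which 2 pairs have identical counts, so its tests support no claim. Lists with a Benjamini-Hochberg adjusted p under 0.05 over the 32 lists of a comparison were called. camera was repeated with an estimated correlation, and fry tested whether members move 1 way on balance. Members were also counted with p adjusted over the list alone.

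Named genes were, per stated comparison, the 10 largest rises and the 10 largest falls among called genes with mean log2 CPM above 1 and no overlap between groups, the up to 4 members with the smallest adjusted p of each list that was called or had at least 2 called members, and a fixed set (Rag1, Rag2, Tcra or Trac, Reg3b, Reg3g, Saa1, Saa2, Il22, Il17a, Cd36, Fabp1, Fabp2, Scd1, Fasn, Apoa4, Slc10a2 and Nfil3). Tcra and Trac were not analysed here.

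The alternatives were relative log expression factors, library size only, no filter, a filter of over 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, an adjusted p under 0.05, an added minimum of 1 on the log2 scale, a fit that is not robust, removal of genes with over 1% of the counts of any library, and leaving out each mouse in turn.

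The fit was tested on simulated data with known changed genes drawn from the real means and library sizes. For Rag1−/− against wild type (15695 genes) it recovered 53.7% of 1.5-fold, 83.6% of 2-fold and 98.5% of 4-fold changes, with 2 false among 170 calls. For the housing comparison (15690 genes) the shares were 47.8%, 82.1% and 98.5%, with 4 false among 167 calls. In each simulation, a changed list of 12 genes was called and 0 of 20 unchanged lists were. Genes were drawn independently there, so the simulation does not measure false calls of lists whose members vary together. Changed genes were taken from those with a mean above 1 CPM, so the shares recovered do not cover genes of fewer reads. Far fewer genes were changed than were called in the real comparisons, so false calls under such broad changes were not measured.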

Results

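Transcripts of the terminal ileum were counted by RNA sequencing in 12 male mice of 4 groups, with 3 mice per group and 1 library per mouse. Rag1−/− mice lack an enzyme that joins antigen receptor segments and so form no mature T or B cells. Tcra−/− mice lack the T cell receptor alpha chain and so form no conventional alpha beta T cells. Total counts ran from 42717064 to 50581616 in Rag1−/− mice, from 42067145 to 42312100 in wild type mice, from 37061276 to 43496528 in co-housed Tcra−/− mice and from 40294353 to 44574864 in separately housed Tcra−/− mice. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.987 to 0.992 in the 12 pairs of mice within a group and 0.942 to 0.983 in the 54 pairs between groups. Reg3b, which encodes an antimicrobial lectin of the epithelium, alone took 5.54 to 5.82% of the counts in Rag1−/− mice, 4.95 to 6.04% in co-housed Tcra−/− mice, 0.905 to 1.77% in wild type mice and 0.260 to 0.662% in separately housed Tcra−/− mice. The first principal component held 47.5% of the variance, and on it the Rag1−/− and co-housed Tcra−/− mice lay between −45.7 and −35.1, the wild type mice between 17.5 and 26.3 and the separately housed Tcra−/− mice between 52.4 and 65.0.

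**Figure D1:**
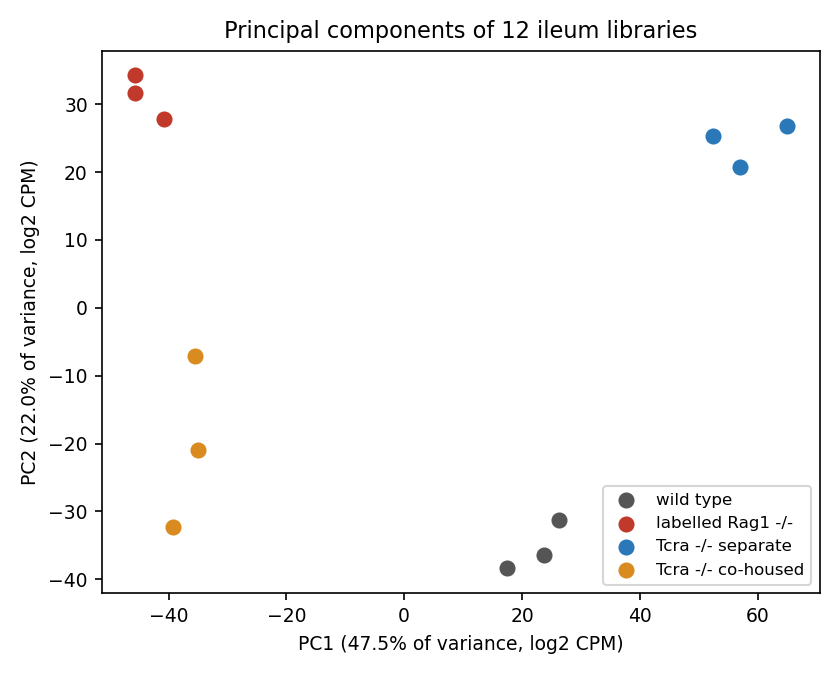
Principal components 1 and 2 of log2 CPM for the 12 libraries, with 1 point per mouse, colour for the group and the percent of variance on each axis (47.5% and 22.0%). Rag1−/− and co-housed Tcra−/− mice share the negative side of component 1 and part on component 2, where the Rag1−/− mice lie between 27.8 and 34.2 and the co-housed mice between −32.3 and −7.13.

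The Rag1−/− label was first checked against the targeted gene. Rag1 (mm9 chromosome 2, 101478411 to 101489689) had 236 reads in the 3 mice labelled Rag1−/−, or 1.81 ± 0.166 CPM (SD, n = 3), and 0 reads in the other 9 libraries. Rag1 was therefore at least 80.5-fold higher than in wild type mice, with a floor of 3 counts over the group, the opposite of a loss of transcript. The part of the gene that is deleted in these mice is not given in the sources used here, so reads of Rag1 do not check the label, and directions below refer to mice labelled Rag1−/−. Transcripts of B cells do follow the label: summed CPM of the B cell list was 14.6 to 17.2 in the mice labelled Rag1−/− and 96.0 to 332 in the other 9 libraries. Rag2, the neighbour of Rag1, had 24 reads in either group and was not called (log2 fold change 0.04, SE 0.67, adjusted p = 0.972). Xist was under 1 CPM in each of the 12 libraries, as the sex on the labels requires.

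The comparison of mice labelled Rag1−/− with wild type mice asks how the ileum differs between these groups. Cage and colony of the mice were not among the factors used, and either could coincide with genotype. B and T cell transcripts fell, along with most genes of antigen presentation by MHC class II. Of 20 genes on the list of the IL-22 and STAT3 epithelial response, 12 rose. Among them was Reg3g, 6.38-fold higher (log2 fold change 2.67, SE 0.35, adjusted p = 0.000384, n = 3 mice per group). B3galt5, a galactosyltransferase gene in none of the lists, was 94.8-fold higher (6.57, SE 0.25, adjusted p = 1.4e-08). Of 28 lipid absorption genes 14 fell and 1 rose, and the fatty acid translocase Cd36 was 2.98-fold lower (−1.57, SE 0.11, adjusted p = 4.5e-08). By the edgeR quasi-likelihood test, 3314 of 15866 genes were called, 1494 higher and 1820 lower, and 1141 of them by over 2-fold (324 higher, 817 lower). The 3 mice of either group did not overlap in 3310 of the called genes and in 45.7% of all genes tested, where chance gives 10%. With library size alone as the scaling, the median of all genes moved from −0.02 to −0.19 and the calls to 713 higher and 3218 lower, so the balance of directions is relative to the scaling.

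Most genes on the list of the IL-22 and STAT3 epithelial response, a pathway of barrier defence, rose in mice labelled Rag1−/−. The list also holds receptors of IL-22, so counts over it do not measure IL-22 signalling. Of the 20 measured, 12 rose, 3 fell and 5 did not pass (13 and 3 adjusted over the list alone), with camera adjusted p = 4.8e-06, and adjusted p = 0.280 with an estimated correlation. Reg3g (chromosome 6, 78416262 to 78418868) had 39269 ± 1130 CPM against 6156 ± 2069 (SD, n = 3). Its paralog Reg3b rose by 2.32 (SE 0.37, adjusted p = 0.00123), and Reg3a by 2.70 (SE 0.27). Reads of such related genes can be assigned to either, which was not measured here. Retnlb, a goblet cell protein with antibacterial activity, rose 62.1-fold to 70.0 ± 8.44 CPM. Fut2, which adds fucose to surface glycans, rose 72.7-fold (6.18, SE 0.42, adjusted p = 7.0e-06). Serum amyloid Saa1 rose by 2.50 (SE 0.43, adjusted p = 0.00237), a call that ended without mouse WTB6x3159 (adjusted p = 0.0137) or WTB6x3160 (adjusted p = 0.0135), and its paralog Saa2 rose by 2.36 (SE 0.30). The 3 members that fell were the receptor subunit Il22ra1 (−0.78, SE 0.11), the decoy receptor Il22ra2 and the antibody transporter Pigr, the last 2 named after their values were seen. Il22 itself rose 16.6-fold (4.05, SE 0.43, adjusted p = 6.8e-06), on 214 reads against 13.

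Type I interferon response genes, which restrict viruses, rose in 9 of 21 cases and fell in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 9.5e-06, and adjusted p = 0.568 with an estimated correlation). The RNA sensor Oas1a rose by 1.51 (SE 0.18, adjusted p = 2.9e-05). Oas2 rose 7.52-fold, with an adjusted p of 0.0121 when only the 6 libraries compared were fitted, and Ifi44 9.02-fold, with 0.0101 there. Cholesterol synthesis had 5 members higher, 1 lower and 17 not called of 23 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0113, and adjusted p = 0.797 with an estimated correlation). Sqle, a rate-setting enzyme of that pathway, rose by 0.76 (SE 0.11) and Fdps by 0.51 (SE 0.09), while Hsd17b7 and Fdft1 were also called higher (Fdft1 was named after its value was seen). Without mouse RAG1x3163 the list's adjusted p was 0.0568, without mouse WTB6x3167 it was 0.0738, and neither is a call. Fry did not call this list (adjusted p = 0.130). The call of Hsd17b7 also ended without mouse WTB6x3160 (adjusted p = 0.0109) and with library size alone (0.0131). Crypt proliferation genes were called as a list on 2 of 20 members higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.00530, and adjusted p = 0.653 with an estimated correlation). Fry did not call that list (adjusted p = 0.0554). The members called were the division gene Birc5 (0.49, SE 0.09), which had an adjusted p of 0.0195 with library size alone, and the cyclin Ccna2 (0.42, SE 0.09). Ccna2 was not called with library size alone (adjusted p = 0.0591) or without mouse RAG1x3163 (0.0149), mouse WTB6x3159 (0.0124) or WTB6x3160 (0.0147).

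The largest rises outside those lists are given here for called genes with mean log2 CPM above 1 and no overlap between groups, which leaves out Rag1. They were Lrg1, a secreted glycoprotein, at 155-fold (7.28, SE 0.69, adjusted p = 6.8e-05), B3galt5 (chromosome 16, 96457408 to 96541465) with 938 ± 181 CPM against 9.89 ± 2.07, and Gml at 31.5-fold. Serpina10, a protease inhibitor, rose 19.6-fold, the tyrosine aminotransferase Tat 17.1-fold, the sulfotransferase Chst4 11.4-fold (adjusted p = 4.5e-10) and the complement factor Cfi 11.1-fold. The predicted gene 1600029D21Rik rose by 4.22 (SE 0.76, adjusted p = 0.00307), a call that ended without mouse RAG1x3164 (adjusted p = 0.0106), mouse WTB6x3159 (0.0138) or WTB6x3160 (0.0117) and in the 6 libraries alone (0.0278), and without mouse WTB6x3167 the rise was 5.57.

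B cell transcripts fell in 19 of 19 cases (19 adjusted over the list alone; camera adjusted p = 2.5e-22, and adjusted p = 0.180 with an estimated correlation). Cd79b, a signalling chain of the B cell receptor, fell 20.6-fold (−4.36, SE 0.19, adjusted p = 9.1e-10), the IgE receptor Fcer2a 146-fold (−7.19, SE 0.36) and the kinase Blk 18.9-fold. T cell transcripts fell in 23 of 24 cases, with Bcl11b the exception (−0.26, adjusted p = 0.0567), and in 23 adjusted over the list alone (camera adjusted p = 4.1e-18, and adjusted p = 0.180 with an estimated correlation). The coreceptor Cd8a fell 15.4-fold (−3.94, SE 0.24, adjusted p = 4.1e-08) and Cd6, an adhesion receptor of T cells, 50.9-fold (−5.67, SE 0.38). Among cytotoxic and intraepithelial lymphocyte genes 12 of 18 fell, 0 rose and 6 did not pass (15 lower adjusted over the list alone; camera adjusted p = 1.9e-07, and adjusted p = 0.413 with an estimated correlation). The integrin Itgb7, which retains lymphocytes in the gut, fell 4.90-fold (−2.29, SE 0.27), the natural killer receptor Klrd1 3.70-fold and the cytokine receptor Il2rb 2.21-fold. Plasma cell genes fell in 6 of 10 cases and rose in 2, Prdm1 and Fkbp11, which were named after their values were seen (7 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000312, and adjusted p = 0.236 with an estimated correlation). The B cell coactivator Pou2af1 fell 43.0-fold (−5.42, SE 0.24, adjusted p = 1.5e-09) and the transcription factor Irf4 22.3-fold. MHC class II genes, which present antigen to helper T cells, fell in 7 of 10 cases and rose in 0 (8 lower adjusted over the list alone; camera adjusted p = 2.8e-05, and adjusted p = 0.413 with an estimated correlation). H2-Ob, a peptide-loading regulator of B cells, fell 20.7-fold (−4.37, SE 0.30), H2-Oa 6.91-fold and H2-DMa, which is found in other presenting cells too, 1.66-fold.

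Lipid absorption genes fell in 14 of 28 cases and rose in 1, Apoc2, named after its value was seen (16 lower and 1 higher adjusted over the list alone; camera adjusted p = 6.2e-05, and adjusted p = 0.549 with an estimated correlation). Cd36 (chromosome 5, 17287508 to 17394777) had 9.95 ± 1.33 CPM against 29.7 ± 3.27 (SD, n = 3). The fatty acid transporter Slc27a2 fell 2.06-fold (−1.04, SE 0.09, adjusted p = 1.8e-07) and the lipid droplet protein Plin2 by 0.86 (SE 0.11). Fabp2, a fatty acid carrier of enterocytes, fell 1.97-fold (−0.98, SE 0.17, adjusted p = 0.000608). Its relative Fabp1 fell 3.91-fold (−1.97, SE 0.39, adjusted p = 0.00452), a call that ended in most fits that left out a mouse of either group. Its adjusted p was 0.0124 without mouse RAG1x3163, 0.0111 without RAG1x3164 and 0.0143 without RAG1x3168. It was 0.0154 without mouse WTB6x3159, 0.0179 without WTB6x3160, and 0.0157 in the 6 libraries alone. The log2 fold change in these fits stayed between −2.16 and −1.70. Apoa4, of lipoprotein particles, did not pass (−0.46, SE 0.22, adjusted p = 0.152). Brush border digestion genes fell in 12 of 20 cases and rose in 0 (13 lower adjusted over the list alone; camera adjusted p = 6.4e-05, and adjusted p = 0.549 with an estimated correlation). The glucose transporter Slc2a2 fell 21.8-fold (−4.44, SE 0.42, adjusted p = 3.1e-05) and the lactase gene Lct 28.4-fold (−4.83, SE 0.62). Xenobiotic and retinoid genes fell in 12 of 24 cases and rose in 2, Isx and Aldh1a1, the latter named after its value was seen (13 and 2 adjusted over the list alone; camera adjusted p = 0.00138, and adjusted p = 0.549 with an estimated correlation). Lrat, which stores retinol as ester, fell 2.54-fold (−1.34, SE 0.13, adjusted p = 8.8e-07) and the cytochrome Cyp2d26 8.36-fold.

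Further lists of rare epithelial cells and of the clock were lower as well. Tuft cell genes fell in 4 of 12 cases (4 adjusted over the list alone; camera adjusted p = 0.0140, and adjusted p = 0.549 with an estimated correlation). The kinase Dclk1 was at −0.74 (SE 0.12) and the channel Trpm5 at −0.95 (SE 0.18). The list was not called without mouse WTB6x3160 (adjusted p = 0.0506) or with library size alone (0.0592). Enteroendocrine genes fell in 3 of 14 cases (4 adjusted over the list alone; camera adjusted p = 0.0201, and adjusted p = 0.687 with an estimated correlation). The hormone Gip was at −0.97 (SE 0.14) and Chga at −0.85 (SE 0.14). Without mouse WTB6x3160 the list had an adjusted p of 0.0544, and with library size alone 0.0570. Circadian clock genes fell in 4 of 17 cases and rose in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0293, and adjusted p = 0.413 with an estimated correlation). Cry2, a repressor of the clock that shares exons with an overlapping gene, was at −1.25 (SE 0.17) and Per2 at −0.95 (SE 0.15), Bhlhe40 and Npas2 were also lower (the latter named after its value was seen), while Nfil3, a repressor tied to fat uptake, rose by 0.74 (SE 0.14, adjusted p = 0.00115). That list had an adjusted p of 0.0575 without mouse RAG1x3163 and 0.149 with library size alone.

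The remaining 17 lists were not called, with camera adjusted p from 0.0983 to 0.908. They were Paneth cell (1 higher and 1 lower of 18, with Guca2b at −0.81), group 3 innate lymphoid cell (2 higher, Il22 and Ncr1, and 7 lower of 18, with Ccr6 at −5.02 and Ltb at −2.71), myeloid cell (Cd14 higher and Cybb lower of 19) and interferon gamma response (Ido1 lower of 22). Fatty acid synthesis had 3 higher (Elovl6, Lpin1 and Me1) and 3 lower (Scd1, Mlxipl and Acacb) of 21, with the desaturase Scd1 down by −1.83 (SE 0.24, adjusted p = 0.000171), and fatty acid oxidation 3 higher (Acadl, Pex11a and Decr1) and 6 lower of 22, with Acadl at 1.87 (SE 0.09). Bile acid handling (Abcc2 lower of 11), goblet cell (3 lower of 13, with Zg16 at −0.80), fibroblast (Fbln1 lower of 12), enteric neuron and glia (Ret higher of 14), adipocyte (2 lower of 10, with Cidec at −1.32), proximal small intestine (Slc40a1 higher and 2 lower of 6) and sex-linked transcripts (Uty higher of 5) had few called members. Smooth muscle, endothelium, red blood cell and immediate early genes had 0 called members of 12, 12, 5 and 15. Some of these lists were called under an alternative. Paneth cell was called upward in the 6 libraries alone (adjusted p = 0.000225) and with library size alone (0.00308). Called downward were group 3 innate lymphoid cell with the CPM filter (0.0242), adipocyte without mouse RAG1x3168 (0.0448) and interferon gamma response without mouse WTB6x3159 (0.0139). Ncr1, Ido1, Me1, Acacb, Decr1, Abcc2, Fbln1, Ret and Uty were named after their values were seen. Median, mean and test differed in sign for fatty acid synthesis (median 0.04, mean −0.11, test upward), enteric neuron and glia (median −0.04, mean 0.05, test upward) and immediate early genes (median 0.04, mean −0.07, test upward). Fasn, the fatty acid synthase, did not pass (0.23, SE 0.09, adjusted p = 0.0654), nor did the bile acid transporter Slc10a2 (0.32, SE 0.15, adjusted p = 0.133). Il17a, with 8 reads against 39, was under the count filter.

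With an estimated correlation, camera called 0 of the 32 lists in this comparison, and 4 had an unadjusted p under 0.05, while fry called 15. Those 15 include group 3 innate lymphoid cell (adjusted p = 0.00777) and goblet cell (0.0304), both downward, in place of cholesterol synthesis and crypt proliferation. The calls of 15 lists by camera, 4 upward and 11 downward, therefore rest on the preset correlation of 0.01.

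The comparison of co-housed with separately housed Tcra−/− mice asks what differs in the ileum after these mice share a cage with wild type mice. Interferon and antigen presentation genes rose in the co-housed mice: Psmb8, a subunit of the immunoproteasome, was 8.72-fold higher (log2 fold change 3.12, SE 0.17, adjusted p = 3.9e-08, n = 3 mice per group) and Cd74, the MHC class II chaperone, 11.3-fold higher (3.49, SE 0.13, adjusted p = 1.7e-10). Of the 20 genes on the IL-22 and STAT3 list, 16 rose, with Reg3g 21.1-fold higher (4.40, SE 0.38, adjusted p = 1.1e-05). B3galt5, outside the lists, was 296-fold higher (8.21, SE 0.27, adjusted p = 2.7e-09). Of 28 lipid absorption genes 20 fell and 0 rose, with Cd36 3.13-fold lower (−1.65, SE 0.11, adjusted p = 1.2e-08) and Fabp1 8.17-fold lower (−3.03, SE 0.40, adjusted p = 0.000225). By the edgeR quasi-likelihood test, 6156 of 15866 genes were called, 3347 higher and 2809 lower, and 1887 of them by over 2-fold (1047 higher, 840 lower). The groups did not overlap in 6143 of the called genes and in 57.9% of all genes tested, where chance gives 10%. With library size alone, the median of all genes was −0.12 in place of −0.01, with 2480 higher and 3695 lower. The separately housed mice carry codes of another form (TCRaSepxT2 to TCRaSepxT4) than the other 9 mice (TCRaCox3155 to RAG1x3168). What the codes stand for is not known here, so housing and a possible difference of cohort cannot be told apart.

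**Figure D2:**
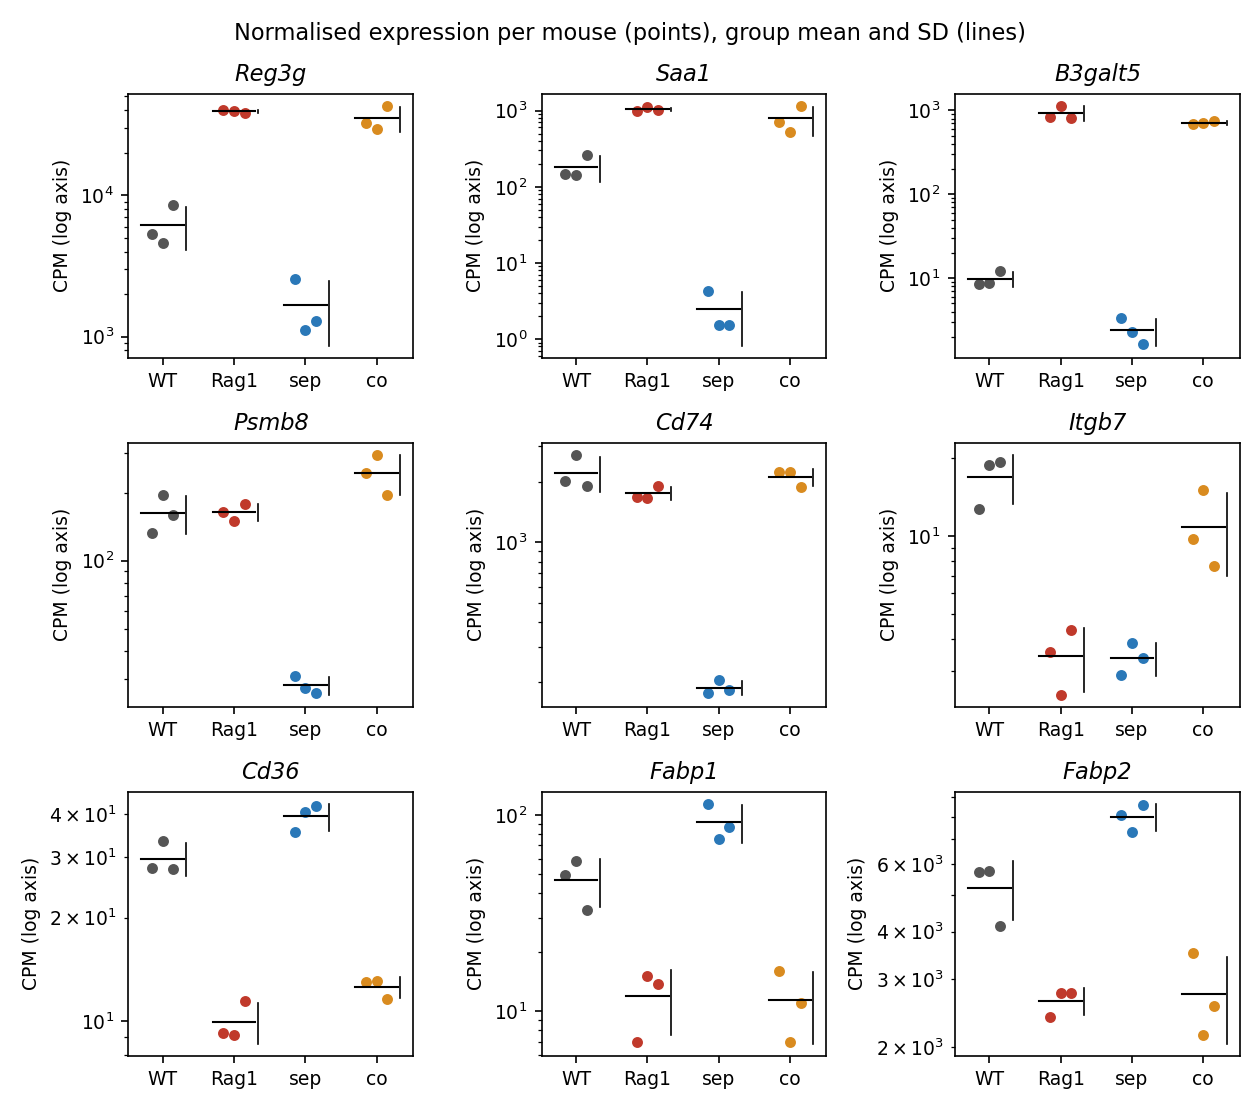
CPM on a log axis of Reg3g, Saa1, B3galt5, Psmb8, Cd74, Itgb7, Cd36, Fabp1 and Fabp2 in the 4 groups, with 1 point per mouse and lines for the mean and SD of 3 mice. Reg3g and B3galt5 were higher, and Cd36 and Fabp2 lower, in mice labelled Rag1−/− than in wild type mice and in co-housed than in separately housed Tcra−/− mice, whereas Itgb7 was lower in the former and higher in the latter comparison.

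On the IL-22 and STAT3 list, 16 of 20 genes rose in the co-housed mice, 1 fell and 3 did not pass (16 and 1 adjusted over the list alone). The list had a camera adjusted p = 2.6e-07, and adjusted p = 0.267 with an estimated correlation. Reg3g had 35103 ± 7146 CPM against 1663 ± 799 (SD, n = 3), and its paralog Reg3b rose by 3.83 (SE 0.39). Saa1 rose 323-fold (8.34, SE 0.58, adjusted p = 4.8e-06; 9.04 without mouse TCRaSepxT2), its paralog Saa2 296-fold and Saa3 15.9-fold (3.99, SE 0.31). Reads within both families can again be assigned to either gene. Fut2 rose 129-fold (7.01, SE 0.45, adjusted p = 2.2e-06). Retnlb had 40.8 ± 11.9 CPM in co-housed mice against 0.0311 (4903 reads against 4, all of them in mouse TCRaSepxT3), a rise of 10.29 (SE 0.50) whose size rests on those 4 reads. The receptor Il22ra1 fell (−1.03, SE 0.11, adjusted p = 1.2e-06). Il22 had 243 reads against 0, at least 90.8-fold higher with a floor of 3 counts over the group. Il17a, with 6 reads against 0, was under the count filter. Among the largest rises, Lrg1 rose by 7.19 (SE 0.70; 6.43 without mouse TCRaCox3157 and 7.90 without TCRaSepxT2), Tat 48.0-fold and Ubd, a ubiquitin-like protein of antigen presenting cells, 91.8-fold (6.52, SE 0.74, adjusted p = 0.000101). Gml rose by 8.19 (SE 0.67; 9.48 without TCRaSepxT2) and the chemokine Ccl8 by 5.74 (SE 0.55; 6.67 without TCRaSepxT3).

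Interferon gamma response genes, which arm cells against intracellular microbes, rose in 22 of 22 cases (22 adjusted over the list alone; camera adjusted p = 8.7e-12, and adjusted p = 0.267 with an estimated correlation). The peptide transporter Tap1 rose 8.75-fold (3.13, SE 0.22) and the proteasome subunit Psmb9 6.74-fold (2.75, SE 0.18). Type I interferon response genes rose in 19 of 21 cases, with Ifi27l2b and Ddx58 not passing (19 adjusted over the list alone; camera adjusted p = 3.5e-08, and adjusted p = 0.299 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose 41.2-fold (5.36, SE 0.30, adjusted p = 4.7e-07), Oas1a 5.15-fold and Bst2, which tethers virus particles, 5.31-fold. MHC class II genes rose in 10 of 10 cases (10 adjusted over the list alone; camera adjusted p = 4.7e-07, and adjusted p = 0.267 with an estimated correlation). Cd74 (chromosome 18, 60963503 to 60972306), which overlaps a microRNA gene, had 2118 ± 206 CPM against 188 ± 14.6 (SD, n = 3), H2-DMb1 rose 11.3-fold and H2-Eb1 5.88-fold.

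T cell transcripts rose in 20 of 24 cases and fell in 0 (22 adjusted over the list alone; camera adjusted p = 1.4e-06, and adjusted p = 0.267 with an estimated correlation). Cd6 rose 5.66-fold (2.50, SE 0.38), the kinase Zap70 4.07-fold and Cd8a 3.27-fold (1.71, SE 0.23). Cytotoxic and intraepithelial lymphocyte genes rose in 15 of 18 cases (15 adjusted over the list alone; camera adjusted p = 2.9e-06, and adjusted p = 0.299 with an estimated correlation). Il2rb rose 4.49-fold (2.17, SE 0.17, adjusted p = 4.2e-08), Klrd1 5.57-fold and Itgb7 3.21-fold. B cell genes rose in 10 of 19 cases (12 adjusted over the list alone; camera adjusted p = 0.000451, and adjusted p = 0.367 with an estimated correlation). Cd79b rose 2.32-fold (1.22, SE 0.15) and Ms4a1, the CD20 antigen, 2.58-fold. Plasma cell genes rose in 6 of 10 cases and fell in 1, Sdc1, named after its value was seen (7 and 1 adjusted over the list alone; camera adjusted p = 0.00435, and adjusted p = 0.267 with an estimated correlation). Igj, the joining chain of secreted antibodies, rose 14.8-fold (3.89, SE 0.36) and Prdm1 2.86-fold (1.52, SE 0.11). Genes of group 3 innate lymphoid cells rose in 7 of 18 cases and fell in 2, among them Kit, named after its value was seen (7 and 2 adjusted over the list alone; camera adjusted p = 0.0360, and adjusted p = 0.267 with an estimated correlation). The chemokine receptor Cxcr6 rose by 1.86 (SE 0.25) and Batf by 1.96 (SE 0.29), and the list was not called without mouse TCRaCox3156 (adjusted p = 0.0512) or with the CPM filter (0.0554). Myeloid cell genes rose in 17 of 19 cases (18 adjusted over the list alone; camera adjusted p = 1.1e-06, and adjusted p = 0.307 with an estimated correlation). The integrin Itgam rose by 1.00 (SE 0.11) and the actin-binding protein Aif1 by 1.14 (SE 0.14). Crypt proliferation genes rose in 15 of 20 cases (15 adjusted over the list alone; camera adjusted p = 2.3e-06, and adjusted p = 0.267 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 1.13 (SE 0.09, adjusted p = 1.0e-07) and Birc5 by 1.23 (SE 0.09).

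Lipid absorption genes fell in 20 of 28 cases and rose in 0 (20 adjusted over the list alone; camera adjusted p = 2.3e-06, and adjusted p = 0.267 with an estimated correlation). Cd36 had 12.6 ± 0.860 CPM against 39.4 ± 3.56 (SD, n = 3), Slc27a2 fell 3.12-fold (−1.64, SE 0.09, adjusted p = 9.4e-10) and Fabp2 2.91-fold (−1.54, SE 0.17). Apoa4 fell 2.87-fold (−1.52, SE 0.23, adjusted p = 0.000253). Fatty acid oxidation genes fell in 16 of 22 cases and rose in 3, Acadl, Decr1 and Pex11a, the last 2 named after their values were seen (16 and 3 adjusted over the list alone; camera adjusted p = 4.1e-05, and adjusted p = 0.267 with an estimated correlation). Ppara, the receptor that drives this pathway, fell 3.01-fold (−1.59, SE 0.11, adjusted p = 2.1e-08) and the thiolase Acaa2 2.16-fold. Xenobiotic and retinoid genes fell in 17 of 24 cases and rose in 1, Isx, named after its value was seen (18 and 1 adjusted over the list alone; camera adjusted p = 1.7e-07, and adjusted p = 0.267 with an estimated correlation). Lrat fell 4.94-fold (−2.31, SE 0.13) and the retinol carrier Rbp2 2.53-fold. Brush border genes fell in 14 of 20 cases (15 adjusted over the list alone; camera adjusted p = 9.5e-06, and adjusted p = 0.312 with an estimated correlation). The peptide transporter Slc15a1 fell 3.09-fold (−1.63, SE 0.12) and the alkaline phosphatase Alpi 2.98-fold. Among the largest falls, Slc28a1, a nucleoside transporter, fell 86.3-fold (−6.43, SE 0.63, adjusted p = 3.5e-05), the retinol dehydrogenase Rdh7 47.2-fold and Pck1, of glucose synthesis, 35.9-fold. Slc2a2 fell by −4.80 on the log2 scale (−5.80 without mouse TCRaCox3155), Lct by −5.70 (−6.60 without TCRaCox3155) and Cyp2d26 by −4.64 (−5.24 without TCRaCox3155).

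Tuft cell genes fell in 10 of 12 cases (10 adjusted over the list alone; camera adjusted p = 0.000253, and adjusted p = 0.267 with an estimated correlation). Their channel Trpm5 was at −1.55 (SE 0.18). Enteroendocrine genes fell in 7 of 14 cases (7 adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.506 with an estimated correlation). Gip was at −0.89 (SE 0.14), and the list was not called without mouse TCRaCox3157 (adjusted p = 0.0771). Smooth muscle genes fell in 3 of 12 cases (3 adjusted over the list alone; camera adjusted p = 0.0157, and adjusted p = 0.540 with an estimated correlation). The kinase Mylk was at −0.51 (SE 0.11), and that list was not called without mouse TCRaCox3155 (adjusted p = 0.0525) or TCRaCox3156 (0.0504). Clock genes fell in 9 of 17 cases and rose in 2, Nfil3 (0.93, SE 0.15, adjusted p = 9.3e-05) and Cry1, the latter named after its value was seen (9 and 2 adjusted over the list alone; camera adjusted p = 0.00568, and adjusted p = 0.267 with an estimated correlation). Cry2 was at −2.14 (SE 0.18) and Npas2 at −1.03 (SE 0.10).

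Camera did not call the other 13 lists (adjusted p from 0.0997 to 0.804). Paneth cell had Pla2g2f higher and Guca2b lower of 18, fatty acid synthesis 2 higher (Elovl6 and Lpin1) and 6 lower of 21, cholesterol synthesis 3 higher (Sqle, Fdps and Acat2) and 4 lower (among them Sc5d, Stard4 and Dhcr7) of 23, goblet cell 2 higher (Agr2 and Clca1) and 4 lower (Zg16, Sytl2, Tff3 and Clca3) of 13, proximal small intestine 1 higher and 3 lower of 6, and enteric neuron and glia 1 higher and 2 lower of 14 (0 and 1 adjusted over the list alone). Bile acid handling had Ostb higher (0.79, SE 0.09) and 3 lower of 11, among them the nuclear receptor Nr0b2, with 0 reads against 203, at least 60.2-fold lower by the floor of 3 counts over the group. Immediate early and heat shock genes had 7 higher and 1 lower, Egr1, of 15, with the near-identical chaperone genes Hspa1a at 4.04 (SE 0.44) and Hspa1b at 3.39 (SE 0.34). Fibroblast (Fbln1) and adipocyte (Cidec) had 1 lower member each of 12 and 10, and endothelium, red blood cell and sex-linked transcripts had 0 called of 12, 5 and 5. Without mouse TCRaCox3157, Paneth cell (adjusted p = 0.0116) and adipocyte (0.0341) were called downward. The co-housed mice differed in Paneth cell transcripts: Lyz1 had 10123 CPM in TCRaCox3157, 4288 in TCRaCox3155 and 2595 in TCRaCox3156, and Defa21 had 1178, 283 and 158. In the separately housed mice Lyz1 had 3471 to 8335 CPM and Defa21 329 to 704. In the 6 libraries alone adipocyte was called downward (0.0458), and without TCRaCox3155 endothelium was called upward (0.0354). Lyz1, Defa21, Lpin1, Fdps, Acat2, Dhcr7, Clca1, Clca3, Egr1, Fbln1 and Cidec were named after their values were seen. Scd1 (0.25, SE 0.23, adjusted p = 0.393), Fasn (0.22, SE 0.09, adjusted p = 0.0486), Slc10a2 (0.30, SE 0.15, adjusted p = 0.114) and Rag2 (0.35, SE 0.69, adjusted p = 0.698) did not pass, and Rag1 had 0 reads in either group. With an estimated correlation, camera called 0 of the 32 lists, 3 had an unadjusted p under 0.05 and fry called 26, so the 19 lists called by camera (11 upward, 8 downward) rest on the preset correlation. Lists that only fry called were bile acid handling, goblet cell, enteric neuron and glia, adipocyte and proximal small intestine downward, and immediate early genes upward. Red blood cell was also called by fry, but Hba-a1 and Hba-a2 carry identical counts, as do Hbb-b1 and Hbb-b2, so its 5 members are 3 distinct values and no direction is drawn from it.

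**Figure D3:**
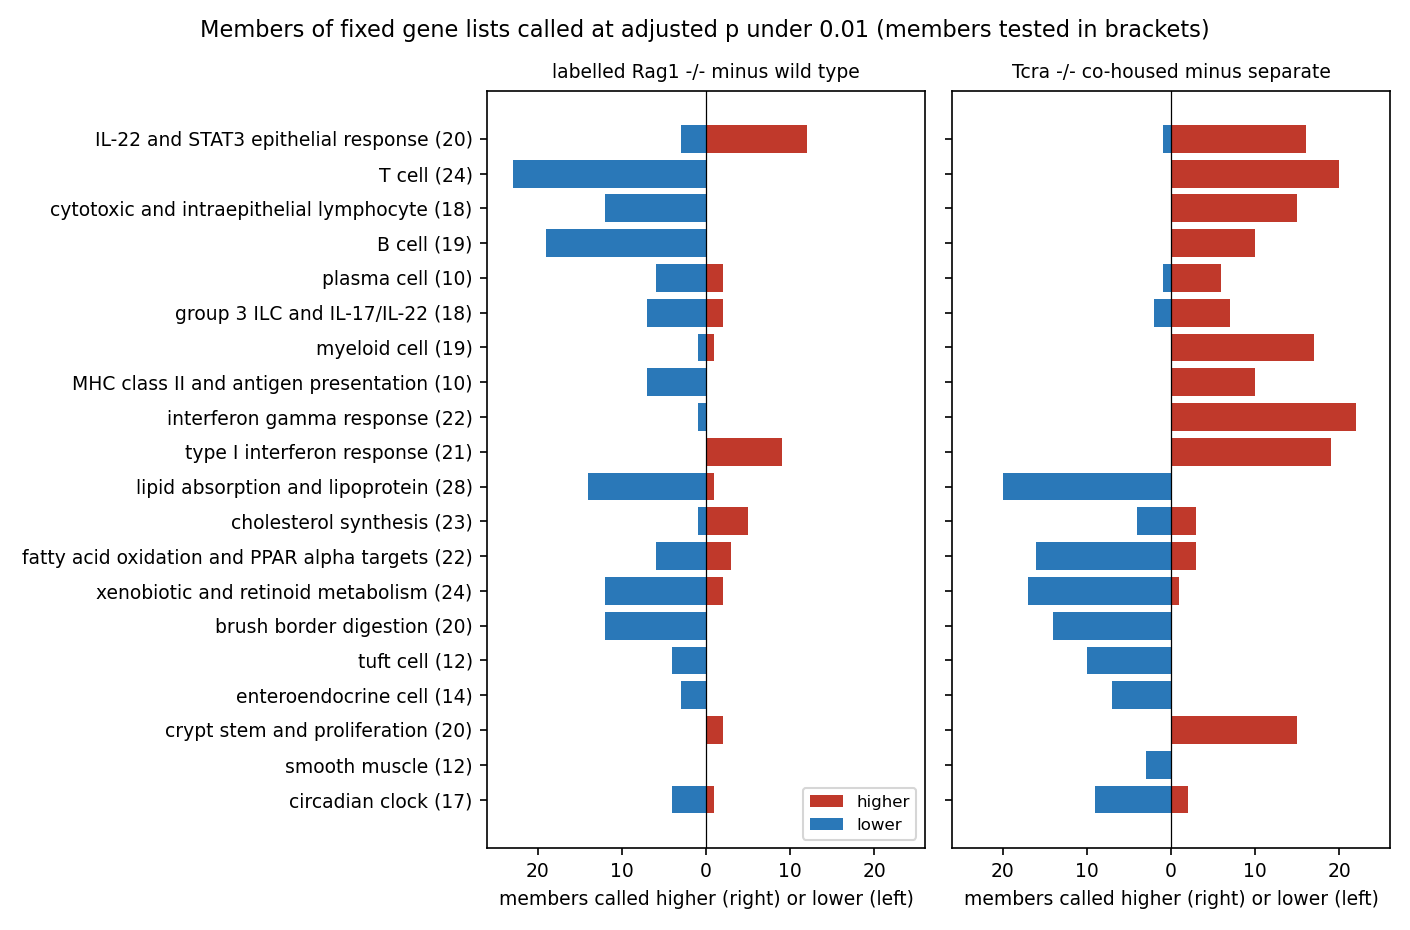
Members called higher (bars to the right) and lower (bars to the left) in each gene list called by camera in either stated comparison, with mice labelled Rag1−/− against wild type and co-housed against separately housed Tcra−/− mice side by side. T cell genes were lower in 23 of 24 cases in the first and higher in 20 of 24 in the second, while lipid absorption genes were lower in 14 and 20 of 28.

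The stated comparisons share no library, but both come from 1 fit with a shared spread per gene. Genes with many reads or a small spread are therefore more likely to be called in both, whatever the direction. Independent calls are thus a reference and no null for the counts below. In total, 2504 genes were called in both. Of these, 2140 (85.5%) went the same way. Higher in both were 1170 genes, against 315 if calls were independent (odds ratio 20.2, 95% interval 17.7 to 23.1), and lower in both 970, against 322 (odds ratio 7.57, 6.81 to 8.42). Reg3g, B3galt5, Fut2 and Retnlb rose in both, and Cd36, Slc27a2, Lrat and Slc2a2 fell in both. Genes higher in mice labelled Rag1−/− and lower in co-housed mice numbered 15, against 265 (odds ratio 0.0420), and the reverse 349, against 384 (odds ratio 0.874, 0.770 to 0.990, Fisher's exact test, two-sided, p = 0.0326). Cd8a, Cd79b, Itgb7 and H2-DMa were among these 349, lower in mice labelled Rag1−/− and higher in the co-housed mice. Across all genes tested, which are not independent replicates, the log2 fold changes had a Pearson r of 0.319 and a Spearman rho of 0.452.

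**Figure D4:**
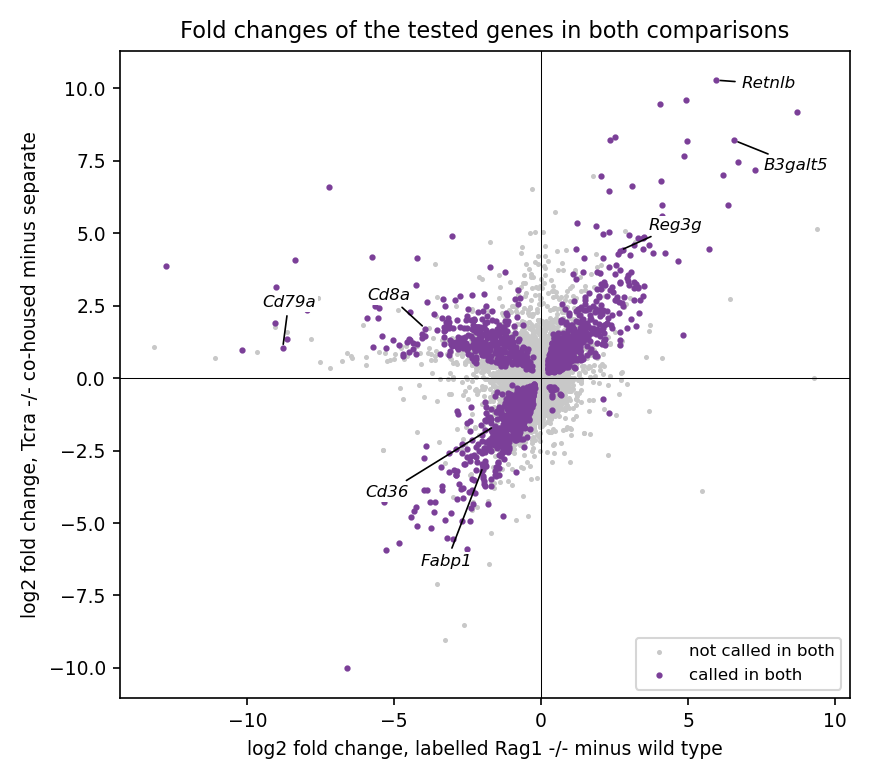
Log2 fold change of each gene tested in mice labelled Rag1−/− against wild type (horizontal) and in co-housed against separately housed Tcra−/− mice (vertical), with genes called in both in purple. Reg3g and B3galt5 lie at the upper right and Cd36 and Fabp1 at the lower left, Cd8a and Cd79a lie at the upper left, and the fitted values of genes unseen in a group depend on the prior count.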

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

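All alternatives were chosen before the data were examined, and each was run. No paired analysis was possible because the groups share no replicate numbers. No call of a named gene or a list in the stated comparisons reversed its direction, and other genes were not compared singly. For named genes of the Rag1 comparison, 1867 of 1985 values kept their side of the threshold, 90 lost it and 28 gained it; in the housing comparison the numbers were 2225, 49 and 17 of 2291. For lists they were 416, 25 and 7 of 448, and 412, 24 and 12 of 448. With library size alone, Rag1 calls were 713 higher and 3218 lower, a shift of the median of all genes to −0.19 that follows from leaving out composition factors. At an adjusted p under 0.05, which admits more genes by construction, 5009 genes were called in the Rag1 comparison (2321 higher), 3850 in separately housed and 4649 in co-housed Tcra−/− mice against wild type, and 3338 in both stated comparisons. With a minimum of 1 on the log2 scale, which admits fewer, 1141 were called in the Rag1 comparison (324 higher, 817 lower), 1887 in the housing comparison (1047 higher, 840 lower), and 773 and 694 in separately housed and co-housed Tcra−/− mice against wild type. Leaving out each mouse gave 2434 to 2809 calls in the Rag1 comparison, 5002 to 5970 in the housing comparison, 1281 to 1735 in separately housed mice against wild type (main value 2182, lowest without TCRaSepxT4) and 2117 to 2524 in co-housed mice against wild type; fewer mice leave fewer residual degrees of freedom, and beyond that the cause was not tested. DESeq2 called 4019, 6723, 2933 and 3627 genes in these 4 comparisons. With an estimated correlation, camera called 0 lists in the Rag1 and 0 in the housing comparison, with 4 and 3 at an unadjusted p under 0.05, in place of 15 and 19; the estimate lets members of a list vary together, and the cause was not tested further. Depth of 37061276 to 50581616 counts limits genes of few reads, such as Rag2 and Il17a.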

Other observations

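Tests around Ptprc, of the differences in enterocyte genes and of the reads of Rag1 were chosen after the result was seen; those around Tcra and Rag1, of Nnt and of the splits were chosen before.

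Compared with wild type mice, separately housed Tcra−/− mice had 2182 genes called, 961 higher and 1221 lower, and 1281 without mouse TCRaSepxT4. The codes of the mice coincide with group here too, so genotype and a possible difference of cohort cannot be told apart. T cell genes fell in 23 of 24 cases (23 adjusted over the list alone; camera adjusted p = 1.0e-19, and adjusted p = 0.121 with an estimated correlation), with Cd8a at −3.35 (SE 0.23) and Cd6 at −5.00 (SE 0.35). MHC class II genes fell in 9 of 10 cases (10 adjusted over the list alone; camera adjusted p = 1.8e-13, and adjusted p = 0.121 with an estimated correlation), with Cd74 at −3.56 (SE 0.13). Interferon gamma response genes fell in 15 of 22 cases (20 adjusted over the list alone; camera adjusted p = 1.5e-15, and adjusted p = 0.190 with an estimated correlation), with Psmb8 at −2.53 (SE 0.17). Genes on the IL-22 and STAT3 list fell in 8 of 20 cases and rose in 1 (13 and 1 adjusted over the list alone), with Saa3 at −3.80 (SE 0.32). That list had a camera adjusted p = 2.1e-08, and adjusted p = 0.141 with an estimated correlation. Fatty acid oxidation genes rose in 11 of 22 cases (12 adjusted over the list alone; camera adjusted p = 2.8e-08, and adjusted p = 0.160 with an estimated correlation), with Pdk4 at 2.41 (SE 0.28). Lists of other tissue layers were also called upward: smooth muscle (2 of 12 members called higher, camera adjusted p = 0.000335, and 0.454 with an estimated correlation), enteric neuron and glia (2 of 14, 0.000519 and 0.190), adipocyte (2 of 10, 0.0387 and 0.503) and fibroblast (1 of 12, 0.0387 and 0.624). A difference in tissue make-up was not tested and stays open. Camera called 21 lists in this comparison, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05 and fry called 18.

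Co-housed Tcra−/− mice differed from wild type mice in 2940 genes, 1482 higher and 1458 lower (24.5% higher with library size alone, where the median of all genes was −0.12). The labels do not say whether these wild type mice were their cage mates, so the contrast may or may not be within a cage. Genes on the IL-22 and STAT3 list rose in 9 of 20 cases and fell in 2 (11 and 3 adjusted over the list alone), with Retnlb at 5.18 (SE 0.31). That list had a camera adjusted p = 9.6e-05, and adjusted p = 0.371 with an estimated correlation. Type I interferon response genes rose in 14 of 21 cases (17 adjusted over the list alone; camera adjusted p = 1.1e-08, and adjusted p = 0.371 with an estimated correlation), with Oas1a at 1.65 (SE 0.18). T cell genes fell in 10 of 24 cases (11 adjusted over the list alone; camera adjusted p = 6.5e-07, and adjusted p = 0.371 with an estimated correlation), with Cd5 at −3.83 (SE 0.34). Lipid absorption genes fell in 12 of 28 cases and rose in 0 (17 and 1 adjusted over the list alone; camera adjusted p = 3.2e-06, and adjusted p = 0.371 with an estimated correlation), with Cd36 at −1.24 (SE 0.11). B cell and MHC class II genes had 0 called members of 19 and 10, with camera adjusted p of 0.112 and 0.179, and adjusted p = 0.737 with an estimated correlation for both. Camera called 12 lists, and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05 and fry called 15.

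Some genes shifted against wild type in every knockout group, and DNA of another mouse strain is a candidate explanation. Such DNA linked to Rag1 or Tcra would not cover Ptprc, which lies on chromosome 1. A shift shared by all knockout groups could also lie on the side of the wild type mice. Genes called 1 way in both Tcra−/− groups against wild type and not between the housing groups numbered 124, and 9 of 194 tested genes within 10 Mb of Dad1, the neighbour of Tcra, were among them (4.64%, against 0.734% elsewhere; odds ratio 6.58, 95% interval 2.89 to 13.2, Fisher's exact test, two-sided, p = 2.1e-05; 2.55% of 15230 windows had as high a share), among them Ppp1r3e at −1.87 and −2.50, as strain DNA around Tcra predicts. Around Rag1 the odds ratio of called genes was 1.73 (1.03 to 2.82, Fisher's exact p = 0.0271, 2.77% of windows), and around Ptprc, for the 166 genes called 1 way in all 3 knockout groups, it was 15.8 (8.52 to 27.8, Fisher's exact p = 1.4e-13, 0.171% of windows), with Sox13 at 1.46, 1.36 and 1.37 in separately housed, co-housed and Rag1−/− labelled mice. Of the 16 such genes in that window, all but Cdc73 (from 145454629) lay between 132697479 and 137180661, on 1 side of Ptprc (139959438 to 140071882). The share of the window therefore does not place these shifts at Ptprc itself. Members of that window other than Sox13 differed between groups, such as Lax1 at −2.24, −0.73 and −4.05 and Pm20d1 at −0.76, −2.09 and −1.75. Fixed strain DNA alone does not predict such differences. Pigr, also in that window, belongs to the IL-22 and STAT3 list, so other causes stay open there. Nnt, partly deleted in 1 substrain, was at −1.19 in co-housed and −0.66 in separately housed Tcra−/− mice and −1.34 in mice labelled Rag1−/−. It was also lower by 0.54 in co-housed than in separately housed mice, which a fixed deletion does not predict. Outside these windows, Pyroxd2 on chromosome 19 was at −2.59, −2.63 and −2.51 in separately housed, co-housed and Rag1−/− labelled mice. Its neighbour Hps1 was at −0.82, −0.73 and −0.65, and Pdcd11 on that chromosome at 0.40, 0.44 and 0.43. These genes were named after their values were seen, and no window around them was tested by itself. All these comparisons share the wild type libraries, Ren1 and Ren2 near Ptprc carry identical counts, and an effect of the knockouts on neighbouring genes stays open and untested around Rag1 and Tcra. Ptprc lies on another chromosome than either, so that explanation does not cover its window.

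Lower enterocyte genes in co-housed mice may stem from a difference of tissue or time, and the tests left each of these open. Of 5 distal ileal genes, 1 was called higher (Ostb at 0.79) and Osta lower (−0.38, with adjusted p of 0.0198 without TCRaCox3156 and 0.0175 without TCRaSepxT4). Of 6 proximal genes, 3 were called lower (Lct at −5.70, Fabp1 at −3.03 and Gata4 at −0.37) and 1 higher (Slc40a1 at 2.36). The call of Gata4 ended without mouse TCRaCox3155 (adjusted p = 0.0192), TCRaCox3156 (0.0311), TCRaSepxT2 (0.0176) or TCRaSepxT4 (0.0357). Another segment of ileum was therefore neither required nor excluded. For another time of collection, Npas2 was at −1.03 with Nr1d1 at −3.57 and Dbp at −2.25, while Arntl (−0.21) and Clock (−0.26) were not called, which decides neither way. For another cohort of separately housed mice, 85.5% of genes called in both stated comparisons went 1 way. A cohort marked by the codes would coincide with housing, so housing and such a cohort cannot be told apart. An effect of sharing a cage with wild type mice stays among the open explanations.

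Reads of Rag1 in mice labelled Rag1−/− could point to a mislabelled sample, which the B cell list argues against, since its highest summed CPM in those mice was 17.9% of the lowest elsewhere. Transcription spread over the locus was left open, since the log2 fold change of Rag2 was 0.041 (SE 0.67) on 24 reads in either group. A targeting construct that still gives reads over Rag1 was not tested.

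Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. Every split but the real one mixes the groups, so group differences add to its spread within groups. Low counts in those splits follow from this and are no null for the real count. In the Rag1 comparison 1 split, the real one, gave 3314 genes by edgeR and the highest other 0 (760 at an unadjusted p under 0.05). In the housing comparison the real split gave 6156 and the highest other 0 (1150 at an unadjusted p under 0.05). Against wild type, the real splits gave 2182 for separately housed and 2940 for co-housed Tcra−/− mice and the highest others 0 and 0 (1274 and 1139 at an unadjusted p under 0.05).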
